A study of Homo sapiens with 14 samples.

How the data were processed

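The 14 libraries are bulk RNA sequencing libraries of human cancer cell lines. Per the labels' protocols, poly(A) RNA was captured on beads, fragmented and copied into cDNA with random hexamers. Per the submitters' processing notes, reads were handled with fastp 0.23.4, STAR 2.7.11a and featureCounts 2.0.6 on hg38. The strand setting of the counting is not given in the sources used here, so reads of overlapping genes on opposite strands, and of near-identical copies, could have been split or shared. The deposited values are integer counts per gene and library, with a symbol and a position for each Ensembl identifier. The table held 62702 lines, of which 3 broken lines belonging to 1 gene (ANK2) were not used, which left 62699 genes. All 14 count columns matched a sample, and all 62699 identifiers matched the reference table of gene names.

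Samples were grouped from the labels by cell line and treatment. Each of 4 lines gave 1 control siRNA library and 2 ADAR siRNA libraries, numbered 1 and 2. Whether the numbers stand for repeats of 1 siRNA or for different siRNAs is not given in the sources used here. MDA-MB-231 also gave 1 NOP14 overexpression library and 1 control library named PCDH. The p-values therefore measure only the spread between samples whose origin as separate cultures is not stated.

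Gene tests were run in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr, libraries scaled with TMM, and changes tested with robust quasi-likelihood fits and Benjamini-Hochberg adjustment at 0.05. Over the 4 lines, the 2 ADAR siRNA libraries of a line were summed, which gave 8 columns, and the fit held cell line and treatment with 3 residual degrees of freedom. Within each line, a fit of 8 groups to the 12 siRNA libraries compared the ADAR siRNA pair with the lone control, with 4 residual degrees of freedom. The spread in that fit came only from the differences between libraries 1 and 2 of a line. The lone control was thus assumed to vary like the ADAR siRNA pairs. The same fit tested whether the response differed between lines with an F test of the interaction. Errors printed after ± are standard errors of the log2 fold change from these fits. NOP14 overexpression has 1 library per arm, so log2 ratios of TMM-scaled CPM (counts scaled to a common library size) with a prior count of 2 are given with no test. The counting intervals cover 95% and, like the floors of 3 counts used for groups at 0, cover counting error only. Spearman's rho was taken across genes, which are not independent replicates.

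The 30 gene lists were fixed before the data were examined, as were the tests, the main alternatives and the rule for named genes. Lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation and with fry, which asks only whether a list's genes move, on balance, one way. For NOP14, each list's median was placed among 10000 random lists matched on mean expression. The rule named ADAR, ADARB1 and NOP14, and over the 4 lines the 12 largest rises and 12 largest falls among genes with adjusted p under 0.05, an average log2 CPM of at least 1 and 1 direction in all 8 ADAR siRNA libraries. Within a line it named the 5 largest rises and falls, between lines the 6 smallest p, in each list the 3 members with the smallest p, and for NOP14 the 12 largest ratios each way at a CPM of at least 5. Other genes are named where a count was 5 or fewer or as stated. Some genes that met the rule, and a test that rested on 1 of them, are not reported here.

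The alternatives were median-ratio scaling, library totals, other count filters, DESeq2 1.42.0, unsummed libraries, ADAR siRNA libraries of 1 number, fits with and without terms for line or number, protein-coding genes alone, and leaving out each line or library. Motifs of 7 bases were scored in 3' UTRs, and runs of 100 neighbouring genes along the genome, with Python 3.11.15 and the GENCODE 29 annotation.

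The gene tests, camera, the random lists, the motif step and the chromosome runs were tested on simulated data, and the correlations were not. Over the 4 lines, with 21944 genes, 76% of 2-fold and 98% of 4-fold changes were recovered and 23 unchanged genes were called. Within 1 line, with 23959 genes, 12% and 65% were recovered with 8 unchanged genes called. For a difference between lines, with 23959 genes, 2% and 23% were recovered with 5 unchanged genes called. In each of these runs unchanged genes made up more than 0.05 of the calls, so the threshold was not held there. A mitosis list lowered by 0.5 on the log2 scale was called with the preset correlation and not with an estimated one. The simulated genes were independent of each other, so lists of correlated genes were not tested. A 7-base motif planted in 1428 of 9126 genes ranked 1 with t = -10.9, where the largest absolute t without planting was 3.76. A run of 100 neighbouring genes lowered by 0.5 among 11299 genes was found as the largest shift (0.417, against 0.165 without planting), though 0 of the 100 non-overlapping windows then passed 0.3, as against 0 without planting. Among the random lists for NOP14, with 13984 genes, mitosis genes raised by 0.2 lay at percentile 100. With nothing planted they lay at 99.85, and 2 of the other 29 lists lay outside the central 95%, so single percentiles near either end also arise without any change.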

Results

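RNA sequencing measured transcript levels in 14 libraries from 4 human cancer cell lines. MDA-MB-231 and BT-549 are triple-negative breast cancer lines, NCI-H1395 is a lung adenocarcinoma line and AGS is a gastric adenocarcinoma line. In each line, cells with an siRNA against ADAR (2 libraries) were compared with cells with a control siRNA (1 library). An siRNA is a short double-stranded RNA that directs the cleavage of a matching transcript. ADAR encodes ADAR1, the enzyme that edits adenosine to inosine in double-stranded RNA. In MDA-MB-231, overexpression of NOP14, a nucleolar protein needed to make the small ribosomal subunit, was compared with a control named PCDH, with 1 library each. The study asked how ADAR1 and NOP14 act on transcriptional output. Total counts per library ranged from 13338338 to 27828376.

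ADAR (ENSG00000160710.18; hg38, chromosome 1, 154581695 to 154628013) fell in all 4 lines. Its level was 313 CPM with control siRNA and 99.0 and 104 CPM with ADAR siRNA in MDA-MB-231, which left 31.7% and 33.3%. It was 788 against 103 and 90.5 CPM in BT-549, 396 against 42.2 and 45.7 CPM in NCI-H1395, and 740 against 127 and 174 CPM in AGS. In BT-549, NCI-H1395 and AGS 10.7% to 23.6% was left, less than in MDA-MB-231. Within lines, edgeR's quasi-likelihood test gave log2 fold changes of -1.60 ± 0.26 in MDA-MB-231 (adjusted p = 0.00663), -3.04 ± 0.26 in BT-549 (1.78e-06), -3.16 ± 0.26 in NCI-H1395 (9.45e-07) and -2.27 ± 0.25 in AGS (0.000287), with 2 ADAR siRNA libraries against 1 control each. Over the 4 lines the change was -2.50 ± 0.29 and missed the threshold (edgeR adjusted p = 0.0996), and without MDA-MB-231 it was -2.80 ± 0.17 (6.5e-06). For the depth of the fall, edgeR's F test of a difference between lines gave an unadjusted p of 0.0015 for ADAR. Adjusted over all genes tested, it did not pass the threshold (adjusted p = 0.516).

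NOP14 (ENSG00000087269.16; hg38, chromosome 4, 2937933 to 2963406) reached 856 CPM in the overexpression library and 130 CPM in PCDH, 6.56-fold more. With ADAR siRNA its log2 fold change over the 4 lines was -0.16 ± 0.10 (edgeR adjusted p = 0.592, 4 lines). In libraries 1 and 2 it stood at 77.7% and 90.6% of the control in MDA-MB-231 and 106% and 67.4% in BT-549. It stood at 117% and 62.4% in NCI-H1395 and 94.5% and 78.8% in AGS. Between libraries 2 and 1 the log2 difference of NOP14 was -0.39 (edgeR adjusted p = 0.391). Its level differed between the control libraries of MDA-MB-231, with 351 CPM with control siRNA against 130 CPM with PCDH. ADARB1 (ENSG00000197381.18), the second catalytically active editing enzyme, stood at 0.16 ± 0.13 over the 4 lines (edgeR adjusted p = 0.687). ADAR itself was at 327 CPM with NOP14 overexpression and 346 CPM with PCDH.

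**Figure D1:**
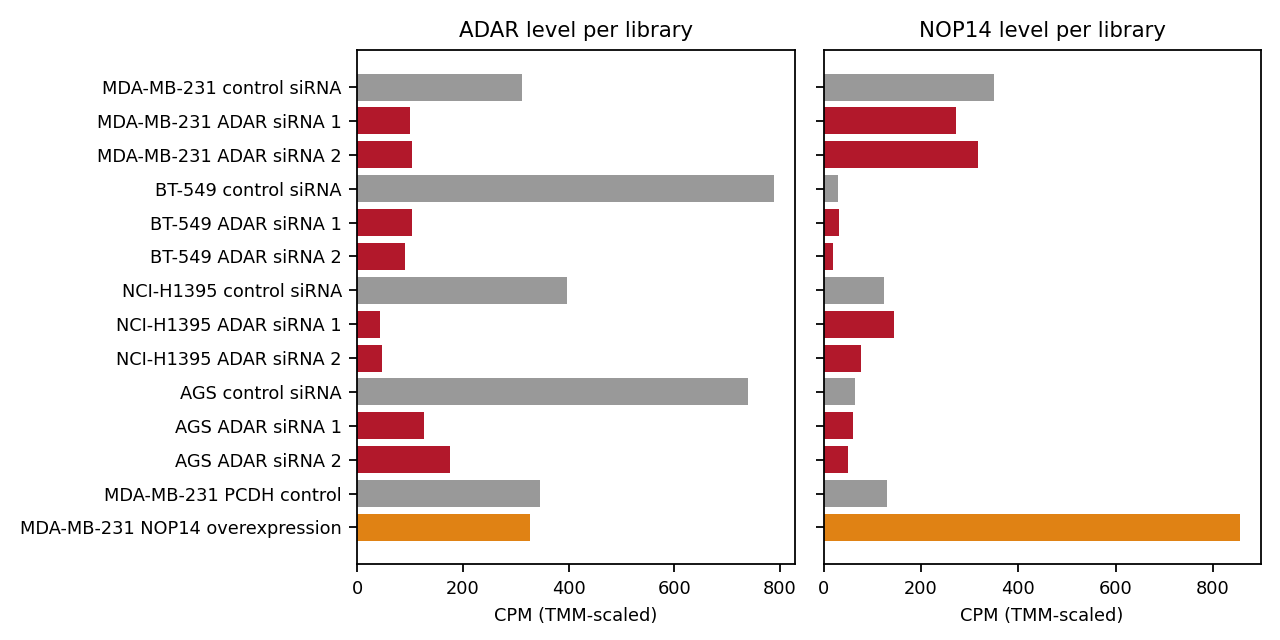
Bars give the TMM-scaled CPM of ADAR (left) and NOP14 (right) in each of the 14 libraries, with control libraries in grey, ADAR siRNA in red and NOP14 overexpression in orange. ADAR lies at 10.7% to 33.3% of the control of the line in the 8 ADAR siRNA libraries, and NOP14 is highest, at 856 CPM, in the overexpression library.

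Over the 4 lines, 4 genes were called with ADAR siRNA, by a test that also called unchanged genes in simulated data. ARRDC3 (ENSG00000113369.9; chromosome 5, 91368631 to 91383317), an arrestin-domain adaptor for receptor traffic, rose by a log2 fold change of 0.98 ± 0.13 (edgeR adjusted p = 0.0217) and was higher in 7 of 8 libraries. CDKN2B (ENSG00000147883.12; chromosome 9, 22002903 to 22009305), which encodes the cell cycle inhibitor p15, rose by 0.97 ± 0.14 (0.0363) and was higher in BT-549 and NCI-H1395 and in library 2 of AGS (34.3 CPM in the control, 34.4 and 96.8 with ADAR siRNA), with 0 counts in MDA-MB-231. POGLUT3 (ENSG00000178202.14; chromosome 11, 108472112 to 108498405), an O-glucosyltransferase of EGF repeats, changed by -1.02 ± 0.13 (0.0209) and was lower in 8 of 8 libraries. DKK1 (ENSG00000107984.10; chromosome 10, 52314281 to 52318042), a secreted Wnt antagonist, changed by -0.78 ± 0.12 (0.0363) and was lower in 7 of 8. Of these, only POGLUT3 met the rule for named genes, and the other 3 were named after their values were seen. Among 13574 genes with an average log2 CPM of at least 1, 636 were lower and 286 higher in all 8 ADAR siRNA libraries. The 2 libraries of a line share 1 control, so these 8 directions are not independent. How many genes would agree without any change was not worked out. Near the threshold stood TSC22D1 (0.67 ± 0.11, higher in 8 of 8) and PNRC1 (0.96 ± 0.16, higher in 8 of 8), each at an edgeR adjusted p of 0.082, picked after their values were seen. Of 21944 genes tested, 2523 had an unadjusted p under 0.05, where 1097.2 would be expected without any change. The count of 4 rested on the lines and the tool: it was 75 without MDA-MB-231, 0 without BT-549 (edgeR, 2033 at unadjusted p under 0.05) or without NCI-H1395 (1608), and 707 with DESeq2. With the 12 libraries unsummed it was 1, which was none of these 4 genes. CDKN2B and POGLUT3 also differed between ADAR siRNA libraries 2 and 1, by 1.06 (edgeR adjusted p = 7.7e-05) and -0.88 (0.000388).

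Genes for cell division and DNA synthesis were lower with ADAR siRNA over the 4 lines. All 25 mitosis genes, among them CDC20, which activates the anaphase-promoting complex, BIRC5 (survivin) and UBE2C, lay below 0 with a median of -0.46 (limma's camera, adjusted p = 1.7e-15; adjusted p = 0.366 with an estimated correlation). All 33 DNA replication genes, among them the nucleotide makers RRM2 and TYMS and the initiation factor MCM10, lay below 0 with a median of -0.41 (camera, adjusted p = 4.33e-17; adjusted p = 0.366 with an estimated correlation). Single values were -0.66 ± 0.13 for CDC20, -0.60 ± 0.13 for BIRC5, -0.62 ± 0.13 for UBE2C, -0.57 ± 0.12 for RRM2, -0.57 ± 0.13 for TYMS and -0.52 ± 0.12 for MCM10, and UBE2C also differed between libraries 2 and 1 (-0.74, edgeR adjusted p = 0.0026). Adjusted over the list alone, 20 mitosis and 24 DNA replication genes were called, and 0 over all genes by edgeR (15 and 14 by DESeq2). Of 20 homologous recombination and Fanconi genes, 18 were lower, led by FANCD2, RAD54L and FANCI (median -0.24; camera, adjusted p = 5.6e-07; adjusted p = 0.366 with an estimated correlation), with 9 called adjusted over the list alone and 0 over all genes by edgeR (7 by DESeq2). The medians of these 3 lists were below 0 in each of the 8 ADAR siRNA libraries, though only by 0.02 for DNA replication in BT-549 library 1. In BT-549 the DNA replication list was not called, with 19 of 33 lower and a median of -0.03 (camera, adjusted p = 0.412).

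Genes of the translation and respiration machinery were also lower. Of 76 cytosolic ribosomal protein genes, 75 were lower, among them RPL35A at -0.48 ± 0.11 and RPS15 (median -0.29; camera, adjusted p = 4.37e-25; adjusted p = 0.366 with an estimated correlation), with 52 called adjusted over the list alone and 0 over all genes by edgeR (43 by DESeq2). Of 41 genes of the small-subunit processome, which shapes the small ribosomal subunit, 34 were lower, led by NAT10, IMP4 and UTP18 (median -0.16; camera, adjusted p = 1.39e-07; adjusted p = 0.278 with an estimated correlation), and of 36 large-subunit biogenesis genes 31, led by EBNA1BP2 and DDX56 (median -0.15; 1.14e-05; 0.366 with an estimated correlation). The RNA polymerase I and III genes (22 of 31 lower, led by POLR3K) had an adjusted p of 0.00217 by camera and 0.543 with an estimated correlation, and the RNA polymerase II genes (28 of 37, led by SSRP1) 0.00175 and 0.278 with an estimated correlation. In these 4 lists 0 genes were called adjusted over the list alone and 0 over all genes by edgeR (8, 2, 1 and 4 by DESeq2). Of 83 nuclear respiratory chain genes, 74 were lower, led by NDUFS5, UQCRH and ATP5MC1 (median -0.17; camera, adjusted p = 3.01e-12; adjusted p = 0.278 with an estimated correlation), with 3 called adjusted over the list alone and 0 over all genes by edgeR (17 by DESeq2). Host genes of small nucleolar RNAs, led by SNHG1, were lower in 21 of 30 (0.0132 by camera; 0.543 with an estimated correlation). With the number 1 libraries alone the call was lost for the small-subunit processome (camera, adjusted p = 0.0586), large-subunit biogenesis (0.227), RNA polymerase I and III (0.211) and these host genes (0.245). Of 23 cholesterol synthesis genes 20 were lower, with EBP at -0.65 ± 0.17 (0.00165; 0.543 with an estimated correlation), of which 1 was called adjusted over the list alone. Library totals as the scale moved the median of all genes to 0.115, against 0.06 with TMM.

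Interferon-stimulated genes were lower rather than higher with ADAR siRNA over the 4 lines. Of 37 members, 27 were lower (median -0.14; camera, adjusted p = 0.00253; adjusted p = 0.543 with an estimated correlation), and 1, OAS1, was called adjusted over the list alone and 0 over all genes by edgeR (1 member by DESeq2). OAS1, the double-stranded RNA sensor that feeds RNase L, stood at -0.66 ± 0.13 and was lower in 8 of 8 libraries. The list's median per library ran from -1.35 in NCI-H1395 library 2 to 0.21 in AGS library 2, and with the number 1 libraries alone its median over the 4 lines was 0.01 (camera, adjusted p = 0.363). RNA editing and double-stranded RNA binding proteins, led by ILF2, were lower in 11 of 16 (camera, adjusted p = 0.0308; adjusted p = 0.543 with an estimated correlation), a call lost with library totals (0.0628) and with the number 1 libraries alone (0.211), and their mean was 0.05 where their median was -0.13. Not called were double-stranded RNA sensors (camera, adjusted p = 0.694, with NLRP1 at 0.47 ± 0.12), interferon and chemokine ligands (0.675), NF-kappaB inflammatory genes (0.479) and MHC class I presentation (0.0502; 0.0383 with median-ratio scaling). The p53 targets (0.772), apoptosis regulators (0.667), endoplasmic reticulum chaperones (0.694), hypoxia and glycolysis (0.777), mitochondrially encoded (0.195), epithelial (0.694), lung and stomach lineage (0.629) and immune cell marker lists (0.24) were not called either. In the hypoxia list, EGLN3, a prolyl hydroxylase induced by hypoxia, stood at 1.09 ± 0.23 and was higher in 8 of 8 libraries, 1 of 5 members called adjusted over the list alone and 0 over all genes by edgeR (1 higher and 1 lower by DESeq2).

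Mesenchymal, stress response, histone and zinc finger genes were higher in the fit over the 4 lines, but not in each line. In MDA-MB-231 libraries 1 and 2 the medians were -0.02 and -0.07 for mesenchymal genes and -0.85 and -0.37 for histones. For zinc finger genes they were 0 in both. In the other 3 lines the mesenchymal and histone medians were above 0 in all 6 ADAR siRNA libraries, and the zinc finger medians ran from 0.0008 to 0.32. Of 25 mesenchymal genes, 21 were higher, led by the collagens COL1A2 (1.12 ± 0.22) and COL3A1 (1.39 ± 0.28) and the matrix protein POSTN (2.18 ± 0.59), with a median of 0.37 (camera, adjusted p = 0.0103; adjusted p = 0.543 with an estimated correlation) and with 4 called adjusted over the list alone and 0 over all genes by edgeR or DESeq2. COL1A2 stood at 744 CPM in the BT-549 control, against 1086 and 2298 with ADAR siRNA, and at 1.56 CPM or less in each library of the other 3 lines, so its value rests on BT-549. The same holds for COL3A1, with 0.38 CPM or less in each library of the other 3 lines, and POSTN, with 0.11 CPM or less. Of 26 integrated stress response genes, 22 were higher, led by ALDH1L2 and SESN2 (median 0.43; camera, adjusted p = 0.0472; adjusted p = 0.791 with an estimated correlation), with ALDH1L2 called adjusted over the list alone. Within lines the stress response list was higher in NCI-H1395 and BT-549 (median 0.20, with 0.35 and 0.03 in libraries 1 and 2; 0.0239; 0.889 with an estimated correlation), not called in MDA-MB-231 (median 0.01; 0.537) and lower in AGS, in 17 of 26 genes (median -0.16; camera, adjusted p = 0.0450; adjusted p = 0.689 with an estimated correlation). Of 12 replication-dependent histone genes 10 were higher over the 4 lines (0.0472; 0.679 with an estimated correlation). Their summed level was 2440 to 4472 CPM in the siRNA libraries of MDA-MB-231 and 19.9 to 476 CPM in those of the other 3 lines, so the pooled value joins unlike libraries. With library totals the p-values of the stress response and histone lists were 0.0509 and 0.0796, and with libraries of 1 number alone the call was lost for mesenchymal genes (0.0576, number 1), histones (0.0964, number 1), endothelial and fibroblast markers (0.371, number 1), the integrated stress response (0.471, number 2) and ZNF genes (0.0549, number 2). Of 485 ZNF genes, which encode zinc finger proteins, 382 were higher, led by ZNF117, ZNF469 and ZNF281 (median 0.18; camera, adjusted p = 0.000117; adjusted p = 0.543 with an estimated correlation), with 0 called adjusted over the list alone by edgeR (over all genes, 8 higher and 1 lower by DESeq2). The 6 measured endothelial and fibroblast markers, led by PDGFRB, were higher (camera, adjusted p = 0.0222; adjusted p = 0.366 with an estimated correlation), several of them near 0 counts. In all, 18 of the 30 lists were called, 5 higher and 13 lower, 16 without MDA-MB-231 and 0 with an estimated correlation.

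**Figure D2:**
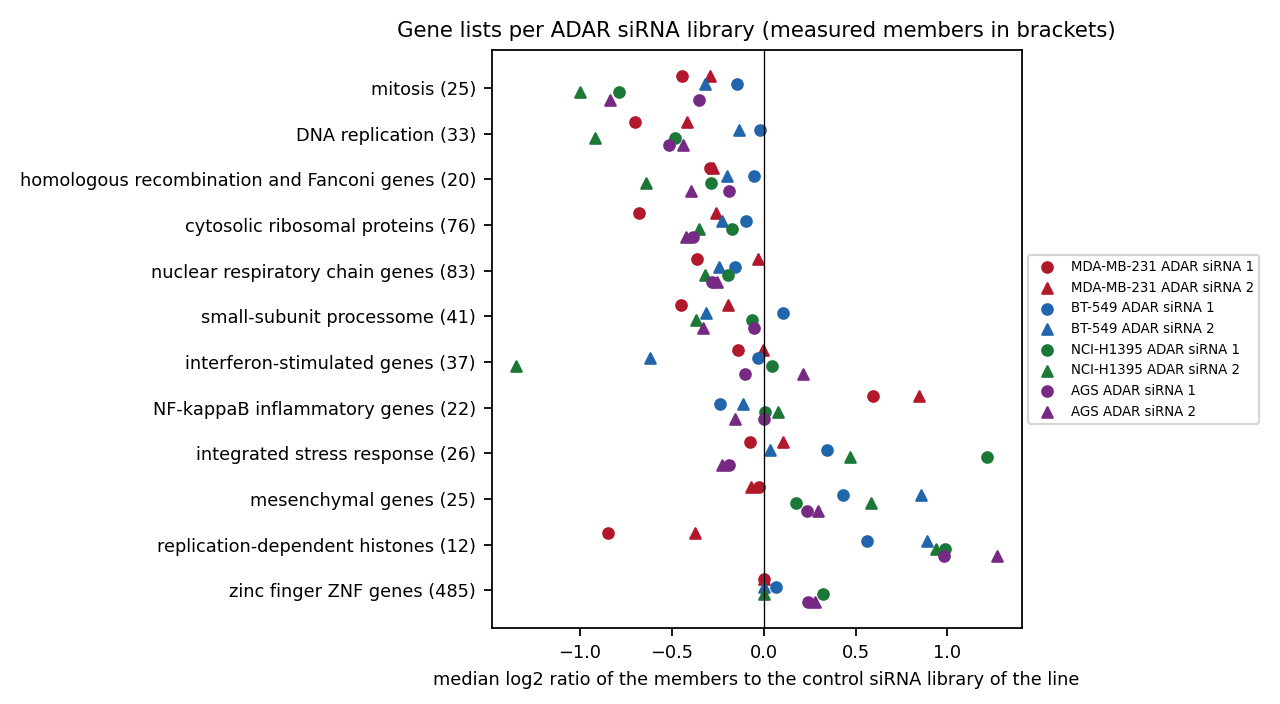
Each point is the median log2 ratio of a list's members to the control siRNA library of the line, in 1 ADAR siRNA library, with circles for library 1, triangles for library 2 and a colour per line. Mitosis and DNA replication lie below 0 in all 8 libraries, and histones lie above 0 in 6 and below 0 in the 2 MDA-MB-231 libraries.

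Within MDA-MB-231, 18 genes changed, 3 higher and 15 lower, several of them genes at or near 0 counts on 1 side. Higher with ADAR siRNA were C14orf132, at 0 counts in the control and at least 29.7-fold higher, GABRA3, a GABA receptor subunit, by 37.8-fold (95% counting interval 10.3 to 316), and the stress cytokine GDF15 by 9.15-fold. Lower were CNKSR2, a scaffold of Ras signalling, by at least 30.1-fold, COX7B2, a cytochrome oxidase subunit, by at least 24.4-fold, and DMD (dystrophin) by 128-fold (22.3 to 5118). THBS2, a matrix thrombospondin, was lower by 26.5-fold (13.6 to 59.2), with 140 counts in the control and 0 and 9 in ADAR siRNA libraries 1 and 2. Floors are taken over the group. The edgeR adjusted p ran from 0.000882 (DMD) to 0.0279 (THBS2) for these 7 genes. In the same libraries whole stretches of chromosomes moved together: 100 neighbouring genes of chromosome 9 (127940582 to 136848801) had median log2 ratios of -0.83 and -0.76, and 6 non-overlapping stretches moved by over 0.3 in both libraries, or 3 once GC content and length were removed, against 0 in the other 3 lines without that correction. The count was 4 without ADAR siRNA library 1 and 2 without library 2, and 1161 genes had an unadjusted p under 0.05 where 1198 would be expected without change.

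**Figure D3:**
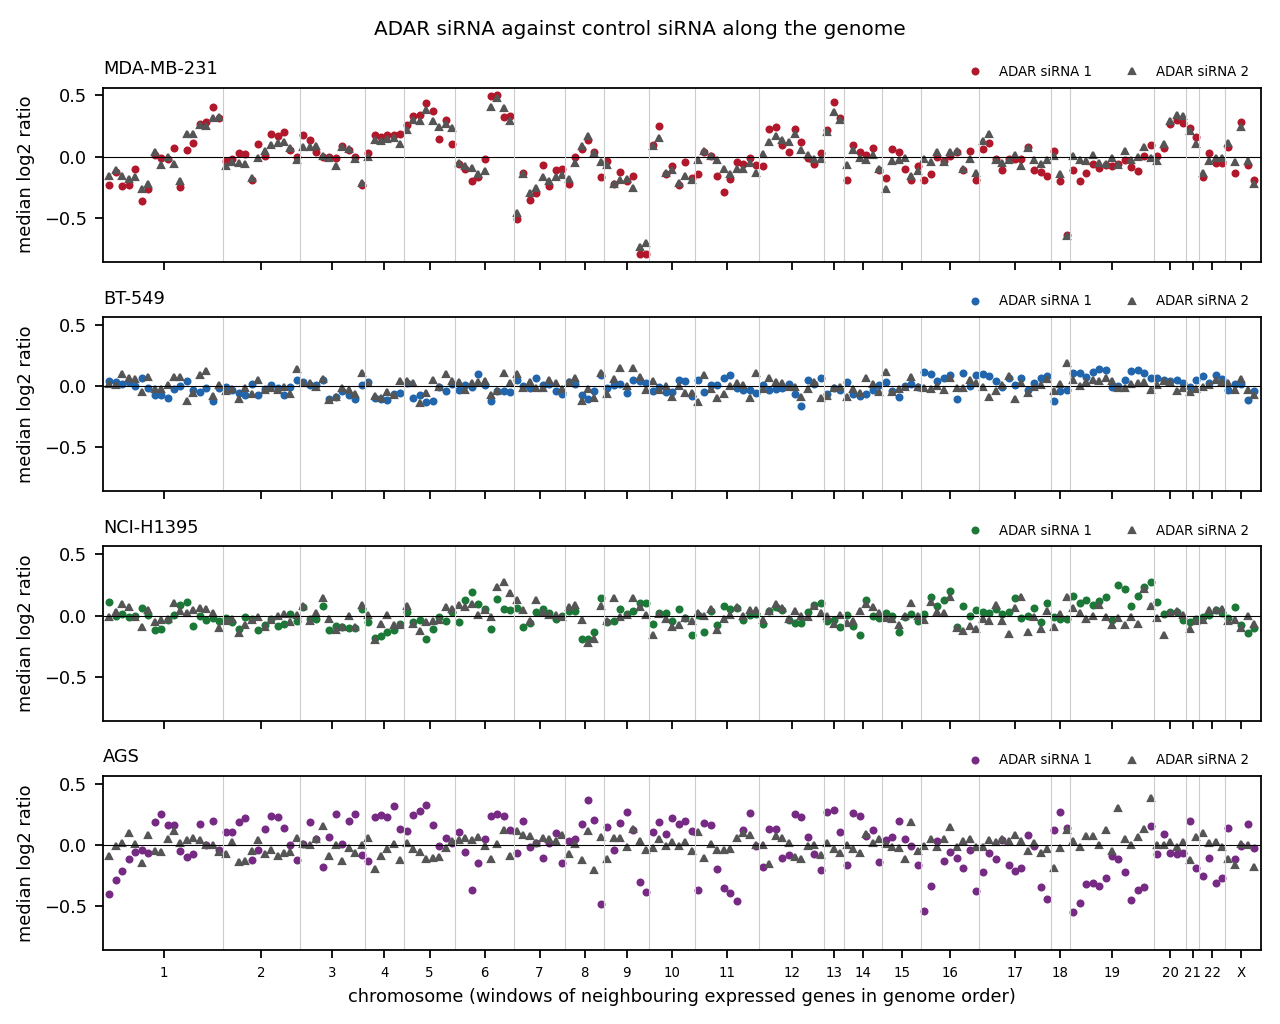
Each point is the median log2 ratio of ADAR siRNA to control siRNA over up to 50 neighbouring genes in genome order, with a panel per line, circles for library 1 and triangles for library 2. Both MDA-MB-231 libraries shift together by chromosome, most on chromosome 9, whereas in AGS library 1 alone spreads widely.

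Inflammatory genes moved up as a list in MDA-MB-231, in the same libraries as the chromosome 9 shift of -0.83 and -0.76. Of 22 NF-kappaB genes, 20 were higher with a median of 0.75 (camera, adjusted p = 1.38e-05; adjusted p = 0.408 with an estimated correlation), with 9 called adjusted over the list alone, 8 of them higher, and 0 over all genes by edgeR (3 by DESeq2). Among these, picked after their values were seen, were the chemokine CXCL2 (1.73 ± 0.41) and the antioxidant enzyme SOD2 (1.22 ± 0.30), while CCL2 was lower. The NF-kappaB list's medians in libraries 1 and 2 were 0.59 and 0.85. The immune cell marker list, with 7 genes measured, was also higher (median 1.26; camera, adjusted p = 0.0382; adjusted p = 0.745 with an estimated correlation), with 0 called adjusted over the list alone and 0 over all genes by edgeR or DESeq2. Ribosomal protein genes (73 of 76 lower, median -0.43) and DNA replication genes (33 of 33, -0.52) were lower (camera, adjusted p = 2.58e-14 and 8.99e-10; 0.745 with an estimated correlation for each), with 1 and 5 called adjusted over the list alone and 0 over all genes by edgeR (1 and 0 by DESeq2). Histone genes had a median of -0.53 in MDA-MB-231 (camera, adjusted p = 0.000696; adjusted p = 0.745 with an estimated correlation). These medians differed between libraries 1 and 2, at 0.47 and 1.13 for immune cell markers (6 genes), -0.68 and -0.26 for ribosomal protein genes, -0.70 and -0.42 for DNA replication and -0.85 and -0.37 for histones (12 genes).

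Within BT-549, NCI-H1395 and AGS, ADAR was the 1 gene called in each line. The spread in this test came from the differences between libraries 1 and 2, which were partly shared by these 3 lines (correlations of 0.57, 0.23 and 0.25). A shared difference counted as spread there, so the small count does not show that few genes responded. At unadjusted p under 0.05 there were 742, 1270 and 1193 of 23959 genes, where 1198 would be expected without change, and DESeq2 called 3, 47 and 14 genes. In NCI-H1395, 23 of 26 integrated stress response genes were higher, median 0.85, with 1.21 in library 1 and 0.47 in library 2 (camera, adjusted p = 5.91e-08; adjusted p = 0.621 with an estimated correlation), with 11 called adjusted over the list alone and 0 over all genes by edgeR (8 by DESeq2). Among them, picked after their values were seen, were SESN2 (2.07 ± 0.40), a leucine sensor, the cystine carrier SLC7A11 (1.82 ± 0.36) and the factor ATF3 (3.18 ± 0.65). The mitosis genes of that line were lower in 25 of 25, median -0.87 (4.83e-17; 0.505 with an estimated correlation), with 20 called adjusted over the list alone and 0 over all genes by edgeR (4 by DESeq2). Its cholesterol synthesis genes were lower in 23 of 23 (3.57e-07; 0.505 with an estimated correlation) and its interferon-stimulated genes in 32 of 37 (4.83e-06; 0.713 with an estimated correlation), with 0 called adjusted over the list alone by edgeR in both lists. The interferon list's median there was 0.05 in library 1 and -1.35 in library 2, so its fall rests on library 2.

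In BT-549 mesenchymal genes were higher in 18 of 25, median 0.72, with 0.43 in library 1 and 0.86 in library 2 (camera, adjusted p = 0.00093; adjusted p = 0.889 with an estimated correlation), with 3 called adjusted over the list alone: POSTN (2.44 ± 0.61), TAGLN, an actin-binding protein of smooth muscle, and FN1 (fibronectin). In AGS mitosis genes were lower in 24 of 25, median -0.55, with -0.35 in library 1 and -0.84 in library 2 (camera, adjusted p = 2.84e-09; adjusted p = 0.689 with an estimated correlation), with 3 called adjusted over the list alone and 0 over all genes by edgeR or DESeq2. Histone genes were higher in BT-549 (median 0.78; camera, adjusted p = 0.000241; 0.889 with an estimated correlation), NCI-H1395 (1.05; 2.22e-05; 0.584 with an estimated correlation) and AGS (1.13; 3.49e-05; 0.689 with an estimated correlation), with 0, 5 and 7 called adjusted over the list alone and 0 over all genes by edgeR (0, 2 and 1 by DESeq2). Their medians in libraries 1 and 2 were 0.56 and 0.89 in BT-549, 0.99 and 0.94 in NCI-H1395 and 0.98 and 1.27 in AGS (12 genes). AGS endoplasmic reticulum chaperones were lower in 14 of 16 (0.00334; 0.689 with an estimated correlation), with medians of -0.21 and -0.59 in libraries 1 and 2. AGS mitochondrially encoded genes were higher in 13 of 13 (0.0457; 0.689 with an estimated correlation), with medians of 0.49 and 0.12, and their share of counts was 3.73% in the AGS control and 5.52% and 4.02% with ADAR siRNA. Differences between lines were not tested for lists.

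The response to ADAR siRNA differed between the 4 lines for 7 genes by edgeR's F test. GDF15 was at 3.53 against 25.9 and 38.0 CPM in MDA-MB-231 and at 2610 against 1268 and 1187 CPM in AGS (adjusted p = 0.0111). PLEKHA7 (ENSG00000166689.18), a protein of adherens junctions, fell from 80.4 to 9.89 and 11.4 CPM in MDA-MB-231 and was at 75.3 against 62.4 and 77.1 CPM in AGS (0.0111). THY1, DMD and the phospholipase PLCB1 were likewise lower in MDA-MB-231 (0.0184, 0.0212 and 0.0212). RN7SL3, named because the count was small, is a copy of the signal recognition particle RNA with near-identical copies, so its value is uncertain (0.0333). No gene was called without the MDA-MB-231 libraries (edgeR, 427 of 21474 at unadjusted p under 0.05) or without its ADAR siRNA library 1 (433) or 2 (501), and DESeq2 called 43 genes in the 4 lines.

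Few transcripts besides NOP14 differed much between NOP14 overexpression and PCDH. After NOP14 itself (log2 ratio 2.72), the largest rises at a CPM of at least 5 were PDXP, a pyridoxal phosphatase, at 1.01 (95% counting interval 0.68 to 1.36), TXNDC5, a disulfide isomerase, at 0.99 (0.70 to 1.30), RGCC, a cell cycle regulator, at 0.83, and the cytokine IL1B at 0.66. The largest falls were the mucin MUC1 at -0.82 (-1.20 to -0.49), ANXA2P2, a pseudogene that shares sequence with ANXA2, at -0.64, the dynein DNAH1 at -0.63 and the antisense transcript SLC9A3-AS1 at -0.61. Further rises were ARID3A, RASEF, OLFM4, NHSL1, PHLDB3, SCART1 and PDF, from 0.55 to 0.65, and further falls CDIP1, ATP6V0C, OAS1, RFX3, MIRLET7IHG, SRPK3, IL32 and CRYL1, from -0.60 to -0.50. Of 13984 genes, 64 differed at least 2-fold, 28 higher and 36 lower. Among the 8689 genes of at least 16 CPM, 1 did, and the SD of the log2 ratio was 0.09. It was 0.89 between the control siRNA and PCDH libraries of the same line, which were unlike libraries (RN7SL1 at 21139 and 3.84 CPM). With 1 library per arm the ratios of NOP14 overexpression to PCDH have no replicate check, and the count of 64 was 2 at a CPM of at least 5.

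Ribosomal protein genes stood a little above PCDH with NOP14 overexpression, 71 of 76 higher with a median log2 ratio of 0.08, above all of 10000 random lists (percentile 100). Nuclear respiratory chain genes (median 0.07, percentile 100), cholesterol synthesis genes (0.07, 99.99), host genes of small nucleolar RNAs (0.07, 99.2) and the small-subunit processome, of which NOP14 is a part and from whose list it was left out (0.03, 98.4), also lay high. Mitochondrially encoded genes (-0.08, percentile 0), interferon-stimulated genes (26 of 35 lower, percentile 0.1), ZNF genes (-0.03, 1.26) and homologous recombination genes (-0.05, 1.33) lay low. Mitosis genes (median 0.01, percentile 54.0) and DNA replication genes (14 of 33 higher, percentile 35.5) lay within the random lists. These percentiles describe the 2 libraries and not the treatment.

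**Figure D4:**
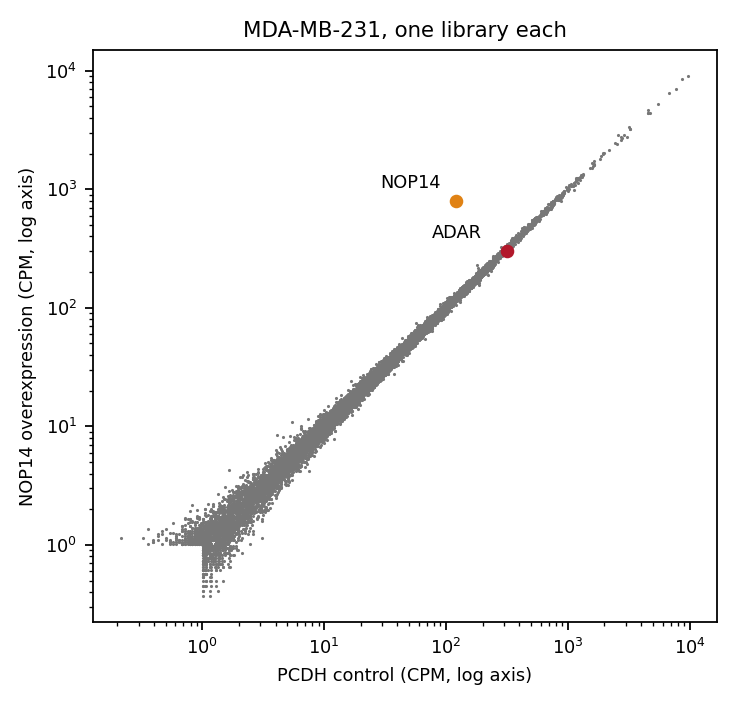
Each point is a gene at its CPM in PCDH (horizontal) and with NOP14 overexpression (vertical), on log axes, with 1 library each. NOP14 lies off the diagonal at 119.8 and 789 CPM, scaled within this pair.

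Across genes, the responses to ADAR siRNA were alike to a varying degree. Spearman's rho of the log2 ratios was 0.38 between BT-549 and NCI-H1395, 0.34 between NCI-H1395 and AGS and 0.23 between BT-549 and AGS. With MDA-MB-231 it was 0.24 for AGS, 0.14 for NCI-H1395 and 0.02 for BT-549, and the median of the 6 pairs was 0.23. The NOP14 ratios, with their own control, gave rho of -0.13 with ADAR siRNA in MDA-MB-231, -0.16 in AGS, -0.01 in NCI-H1395 and -0.00 in BT-549, with a median of -0.07. Genes are not independent replicates, so no p is given.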

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

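The fits without the MDA-MB-231 libraries were chosen only after the result was seen. For 7 genes the ADAR siRNA response differed between the 4 lines by edgeR's F test of the interaction itself, among them GDF15 (adjusted p = 0.0111), PLEKHA7 (0.0111), THY1 (0.0184), DMD (0.0212), PLCB1 (0.0212) and RN7SL3 (0.0333). For 6 of them MDA-MB-231 was the line that stood apart. PLEKHA7 was 7.53-fold lower there with ADAR siRNA (95% counting interval 6.68 to 8.53), PLCB1 9.38-fold lower and THY1 21.7-fold lower, and GDF15 was 9.15-fold higher. RN7SL3 was instead high in all 3 siRNA libraries of MDA-MB-231, at 274 to 366 CPM, against 28.7 CPM or less in each other library.

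The pattern is a set of genes at or near 0 on 1 side of the MDA-MB-231 comparison, 7 of them at least 16-fold apart in both ADAR siRNA libraries (3 higher, 4 lower), against 0 in each of BT-549, NCI-H1395 and AGS, and 0 between ADAR siRNA libraries 1 and 2 of MDA-MB-231. MTAP and CDKN2B had 0 counts in the MDA-MB-231 control siRNA library. In the controls of BT-549, NCI-H1395 and AGS MTAP stood at 188, 85.2 and 52.9 CPM. These values argue against cells of BT-549, NCI-H1395 or AGS mixed into the MDA-MB-231 control, and cells of any other line are not weighed here. A difference in stock or clone between control and ADAR siRNA cells stays open and may explain the pattern: it predicts shifts of runs of neighbouring genes. In both libraries 100 neighbouring genes of chromosome 9 were shifted by at least 0.764 on the log2 scale. The largest shift was 0.703 once GC content and length were removed. In the other 3 lines the largest was 0.107 to 0.195, without that correction. The shift was not even along the arm, since 50 genes before this run (113275642 to 127578989) had medians of -0.16 and -0.26. Against PCDH, 100 neighbouring genes of chromosome 9 were shifted too, by -1.03 and -0.89, with GC content and length not removed. PCDH was an unlike library, with RN7SL1 at 3.84 CPM against 19904 to 25541 CPM in the siRNA libraries of MDA-MB-231. The comparison with PCDH therefore cannot part a difference in stock from a difference in library. CNKSR2, COX7B2, DMD and THBS2 stood at 2.23 to 27.1 CPM in PCDH and with NOP14 overexpression, on the side of the control siRNA library. C14orf132 was at 0.04 CPM in each, whereas GABRA3 (1.57 and 2.13 CPM) and GDF15 (15.6 and 18.2 CPM) lay between control and ADAR siRNA. The gene tests in MDA-MB-231 set each ADAR siRNA library against the 1 control siRNA library. An effect of ADAR loss on these genes was thus not tested apart from a difference in stock or clone. Genotyping or low-coverage DNA sequencing of the control and ADAR siRNA cells, and a control siRNA library from the ADAR siRNA stock, would decide it.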

How the results depend on the processing

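The fits without the MDA-MB-231 libraries, and the lists with 1 ADAR siRNA number or other scalings, were chosen after seeing the data. No result changed direction past its threshold under any alternative run. A limit is that each line has 1 control library, and the counts of genes moved with most choices.

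Over the 4 lines (4 genes), no count filter gave 394 genes (296 higher, 98 lower), the DESeq2 Wald test 707, unsummed libraries 1, number 1 libraries 14 and median-ratio scaling 4. By edgeR the count was 0 at a CPM of at least 1 in 4 libraries (2098 genes at unadjusted p under 0.05), with number 2 libraries (2765), without a cell line term (18) and with protein-coding genes only (2012). Leaving out a line or a library gave 0 to 75: 75 without MDA-MB-231, 0 without BT-549 (2033), NCI-H1395 (1608), NCI-H1395 library 1 (2517) or AGS library 1 (2555), 1 without MDA-MB-231 library 2, BT-549 library 1, BT-549 library 2 or NCI-H1395 library 2, and 2 without MDA-MB-231 library 1 or AGS library 2. The 4 genes were among the 75 and the 707. Fewer lines leave fewer degrees of freedom, and otherwise the cause was not tested.

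Within lines, no count filter gave 107 genes in MDA-MB-231, 27 in BT-549, 72 in NCI-H1395 and 33 in AGS, and DESeq2 53, 3, 47 and 14. A CPM of at least 1 in 4 libraries gave 10 in MDA-MB-231, and median-ratio scaling 2 in AGS. Leaving out 1 ADAR siRNA library of any line gave 2 to 60 genes in MDA-MB-231 (4 and 2 without its own library 1 or 2, 52 and 56 without those of BT-549, 60 and 59 of NCI-H1395, 47 and 48 of AGS). It gave 1 to 32 in BT-549 (32 without its own library 1, 6 without either of NCI-H1395, 3 without either of AGS), 1 to 39 in NCI-H1395 (38 and 39 without its own library 1 or 2, 12 and 14 without those of BT-549, 5 and 4 of AGS) and 1 to 8 in AGS (8 without its own library 1, 5 and 6 without those of BT-549, 6 without either of NCI-H1395). For the difference between lines (7 genes), no filter gave 126, DESeq2 43, a CPM of at least 1 in 4 libraries 0 (edgeR, 559 at unadjusted p under 0.05), and the fit without MDA-MB-231 0 (427). Leaving out 1 library gave 0 to 38, with 0 without MDA-MB-231 library 1 (433) or 2 (501), 22 and 11 without BT-549 library 1 or 2, 38 and 37 without NCI-H1395 library 1 or 2 and 19 without AGS library 1. The cause was not tested.

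Of the 18 lists called, an estimated correlation left 0, fry 1 and number 1 libraries 9, and leaving out a line gave 12 to 16. In the simulated data an estimated correlation also missed a planted list. Simulated genes were drawn independently, so that run cannot show whether the preset of 0.01 holds for the real lists. Without MDA-MB-231 the estimated correlation was 0.68 for mitosis, 0.72 for DNA replication and 0.64 for ribosomal protein genes. It was 0.03 for nuclear respiratory chain genes and -0.01 for the small-subunit processome. For NOP14 (64 genes at least 2-fold apart), a prior count of 10 gave 13 genes, a CPM of at least 5 gave 2 and at least 10 counts in both libraries together 666, since ratios of low counts scatter most. NOP14's own ratio and the correlations kept within their spread.

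A block for the number of the ADAR siRNA libraries was tried because the labels number them 1 and 2. The differences between libraries 2 and 1 correlated at 0.57, 0.23 and 0.25 among BT-549, NCI-H1395 and AGS and at -0.11, -0.07 and 0.12 between MDA-MB-231 and these, so the numbers are shared by 3 lines and do not pair all 4. With this block the counts were 2 over the 4 lines, neither of them among the 4 genes called without it (nor was the 1 gene with unsummed libraries), 187 in MDA-MB-231, 42 in BT-549, 149 in NCI-H1395, 65 in AGS and 210 for the difference, and without the MDA-MB-231 libraries 1 in BT-549, 16 in NCI-H1395, 1 in AGS and 1 for the difference.

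Among single genes over the 4 lines, 1968 values kept their side of the threshold, 62 lost a call, 70 gained one and 1 moved. Among lists these numbers were 183, 64, 4 and 19. Only a gene or list called in the main fit could lose a call. The 62 losses thus all fell on the 4 genes called there, and the 64 on the 18 lists called. Most of the 1968 values belong to genes that were not called and stayed so, and they do not show that calls were stable. Within 1 line the simulated data recovered 12% of 2-fold changes, so most such changes were out of reach at this design.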

Other observations

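The test of ADAR levels between libraries 1 and 2, the scaling test and the choice of splits were made only after the result was seen, as were the genes named here from the 3 lines.

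Without MDA-MB-231, whose libraries showed the shifts of chromosome 9 given above, 75 genes changed over BT-549, NCI-H1395 and AGS (44 higher, 31 lower, 20162 tested), and they include the 4 genes of the 4 lines. TPM4, a tropomyosin of actin filaments, rose by 1.02 ± 0.13 (edgeR adjusted p = 0.00605), from 627 to 1071 and 1308 CPM in BT-549, from 150 to 298 and 363 CPM in NCI-H1395 and from 433 to 883 and 719 CPM in AGS. TGFBI, a matrix protein induced by TGF-beta, rose by 2.24 ± 0.18 (0.000133), more in library 2 than in library 1 (difference 1.84, edgeR adjusted p = 5.17e-19). LOX, which crosslinks collagen, rose by 1.23 ± 0.21, and COL5A2 by 1.35 ± 0.19, COL1A2 by 1.30 ± 0.22 and COL3A1 by 1.43 ± 0.24, though COL1A2 and COL3A1 had 0.38 CPM or less in each library of NCI-H1395 and AGS, so that their calls rest on BT-549. TGFB1, the ligand itself, changed by -0.66 ± 0.12 (0.0333). CALM3, a calmodulin gene, changed by -1.15 ± 0.17 (0.0212), NCAPD2, a condensin subunit, by -0.97 ± 0.15, and CD82, a tetraspanin, by -0.94 ± 0.13. Between libraries 2 and 1, LOX (0.81, edgeR adjusted p = 0.00817), CD82 (1.03, 3.77e-05), TGFB1 (0.85, 0.000182), COL1A2 (1.001, 0.0478) and NCAPD2 (-0.85, 0.000124) also differed, whereas for TPM4 the difference was 0.16 (0.923).

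Replication-dependent histone genes rose in the same 3 lines: H4C8 by 1.70 ± 0.25 (edgeR adjusted p = 0.0106), H2BC5 by 1.38 ± 0.20, H1-2 by 0.99 ± 0.15 and H2AC6 by 0.92 ± 0.13. As a list, 10 of 10 were higher with a median of 0.95 (camera, adjusted p = 2.44e-06; adjusted p = 0.478 with an estimated correlation), with 7 called adjusted over the list alone and 4 over all genes. Most transcripts of these genes lack poly(A) tails, and the labels give poly(A) capture, so these values come from what the capture retained, 19.9 to 476 CPM in sum. The fall in MDA-MB-231 was measured at 2440 to 4472 CPM and is not set against this rise. In the same fit 25 of 25 mitosis genes were lower (median -0.52), with 23 called adjusted over the list alone and 1, UBE2C, over all genes, which also differed between libraries 2 and 1 (-0.74, edgeR adjusted p = 0.0026). Mesenchymal genes were higher in 22 of 25 (camera, adjusted p = 8.98e-05; adjusted p = 0.428 with an estimated correlation), with 11 called adjusted over the list alone and 5 over all genes. Interferon-stimulated genes were lower in 26 of 37 (median -0.10; camera, adjusted p = 0.000565; adjusted p = 0.549 with an estimated correlation), with 6 called adjusted over the list alone and 1, LGALS3BP (-0.72 ± 0.14), over all genes.

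Libraries 1 and 2 of ADAR siRNA differed from each other in a shared way in BT-549, NCI-H1395 and AGS, with 357 genes called between the numbers over the 4 lines (edgeR; 246 higher and 111 lower in library 2), among them NOTUM (2.25), SAMD11 (2.25), LTBP2 (1.47), SOWAHC (-1.64) and PEX2 (-1.16). A deeper knockdown with 1 number is argued against, since ADAR in library 2 was at most 1.38 times that in library 1, and so is bias by GC content and transcript length, which took 8.39% of the variance and left correlations between lines of at least 0.303. siRNAs of different seed sequence stay open and are a candidate explanation: genes with AAATGCA in the 3' UTR were lower in library 2 (t = -13.3) and genes with ATATATG higher (t = 9.23), where the largest absolute t of permuted genes was 5.02. Against the control of the line, genes with ATATATG were lower in library 1 of BT-549, NCI-H1395 and AGS (t = -5.25, -8.22 and -9.03). Genes with AAATGCA were lower in library 2 of the same lines (t = -8.51, -12.8 and -7.65). In MDA-MB-231 no 7-base motif passed the permutations (4.49 against 4.93), and the siRNA sequences or a rescue with siRNA-resistant ADAR would decide it.

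Lower mitosis and DNA replication genes are the second pattern, with all 58 members lower and a median of -0.43. Scaling of the libraries is argued against, since a scale factor moves all genes of a library alike and the members lay 0.494 below the median of all genes. Whether they fell or most other genes rose in absolute terms is not shown by these data. Seed matches in these transcripts as the whole cause are argued against too, since the 40 members without a site of the 5 leading motifs had a median of -0.43 and were all lower. Each line gave 1 control and 1 ADAR siRNA column, so the splits to compare are the 8 that part all 4 pairs, too few for a share under 0.05: the median was -0.434 in the real split and -0.357 in the farthest other (1 of 8 as far). The hypothesis that ADAR loss slowed the cell cycle may be tested by counting cells in S phase and mitosis with several siRNAs per line. For the count of genes over the 4 lines the same 8 splits are too few as well, with 4 genes in the real split and 0 by edgeR in each of the other 7 (1 of 8 with as many). The other 24 splits that could be fitted, of 35 in all, part 2 pairs, so each compares ADAR siRNA with control in only 2 lines, in the same or in opposite directions, and these gave 0 to 2 genes. Over all 32 fitted splits, 9 had a cell cycle median as far from 0 as the real one, the farthest other being -0.583.

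The 3 siRNA libraries of MDA-MB-231 held RNAs that lack poly(A) tails. RN7SL1 stood at 19904 to 25541 CPM there and at 58.7 CPM or less in the other 11 libraries, and RMRP, the RNA of the processing ribonuclease MRP, at 2041 to 3105 CPM against 0.36 CPM or less. Histone genes were higher in the MDA-MB-231 control siRNA library than in PCDH by a median log2 ratio of 4.99, mitochondrially encoded genes had a median of -0.88 and cholesterol synthesis genes -1.59. Between these control libraries 207 genes were at least 16-fold apart, and 1034 of 8652 genes of at least 16 CPM at least 2-fold. MTAP and CDKN2B had 0 counts in each of the 5 MDA-MB-231 libraries.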
